A study of Mus musculus with 12 samples.

How the data were processed

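Messenger RNA was measured in 12 pieces of mouse spleen, 2 pieces from each of 6 animals, by sequencing of unstranded poly-A libraries, per the labels' protocols. The deposited values are read counts per Ensembl gene, one column per piece, as whole numbers that the authors had not normalised, judged from the values themselves. STAR 2.5.3a and limma, and the genome builds mm10 and GRCm38, are named by the submitters' processing notes with no statement of what each was used for. The counting mode and the release of the gene annotation are not given in the sources used here. Because the libraries carry no strand, reads from a gene and an overlapping antisense gene cannot be told apart, and genes with a near-identical copy may share reads.

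The table held 32121 genes, of which 32026 were matched by Ensembl identifier to the GENCODE mouse annotation, release 21 of the GRCm38 build, for symbols and coordinates. The 95 unmatched identifiers held at most 0.027% of a library's counts. Each gene had at least 1 count, 0 entries lacked a gene name, 0 columns belonged to no sample, and no mitochondrial genome genes were among those counted. The libraries held 14320833 to 22031026 counts, and 3 counts were taken as the detection floor. CPM stands for counts scaled to a common library size. Intervals on shares of counts are exact Clopper-Pearson intervals at 95%, and they and the floors cover counting error only.

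The groups came from the genotype labels: 3 animals with VEC-Cre, the Sleeping Beauty (SB) transposase and the onc2 transposon, called SB animals, and 3 wild-type controls. The replicate was the animal. Pieces 1 and 2 of a spleen are paired by the animal named in their titles. For controls they are the sections given as A and B. Comparisons across genotypes treat A as piece 1 and B as piece 2, though no position in the spleen is given. No label links an SB animal to a control animal, so no paired fit across genotypes was made. The 2 pieces of a spleen differed by far more than counting noise, with chi-square per degree of freedom of 6.09 to 41.6 over genes with at least 20 counts, so no library appeared to be deposited more than once.

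The tests, the genes to be named and 28 gene lists were fixed before the data were examined. For the genotype comparison the counts of both pieces of a spleen were summed, and SB was compared with control animals using edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, robust quasi-likelihood fit, two-sided test, Benjamini-Hochberg adjusted p under 0.05). For pieces, the quasi-likelihood test was run on the 12 libraries with the animal as a block, in all animals, within each genotype, and for the difference between genotypes. For animals, a model with 1 coefficient per animal was fitted to the 12 libraries. An F test asked whether the 3 animals of a genotype were equal, and each animal was set against the mean of the others of its genotype. A gene was called particular to an animal when it passed that test and both of its pieces lay outside the range of the other 10 libraries. These animal tests take their error from the spread between pieces of one spleen, and their p-values compare these spleens only.

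Standard errors (SE) of log2 changes were taken from the F statistic. CPM values use TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, on voom values of the summed counts, adjusted over the 25 lists with at least 3 tested genes. Lists were also tested with an estimated correlation and with fry. Distances between libraries were root-mean-square differences of log2 CPM (prior count 2) over the 500 most variable genes, tested by exact permutation of the pairing of pieces. Immunoglobulin V gene usage was summarised by the share of the most used gene and the inverse Simpson index, a measure of the effective number of V genes. Differences between pieces given per animal are on the log2(CPM + 1) scale, which understates the change of low genes.

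The lists were erythroid, heme synthesis, embryonic globin and fetal, megakaryocyte, primary granule, mature neutrophil, monocyte, red pulp macrophage, marginal zone, dendritic, mast and basophil, eosinophil, B cell, plasma cell, T cell, NK cell, stem and progenitor, endothelial, stroma, proliferation, interferon, immediate early, pancreas, adipose, liver, sex, phosphoinositide kinase, and blood regulators and oncogenes. Genes to be named were, per direction, the 10 largest genotype changes among called genes with a mean of at least 5 CPM and no overlap between SB and control libraries, up to 4 called members of each list with the smallest adjusted p, Cdh5 and Pi4ka whatever their p, the 5 called piece genes of smallest adjusted p in each direction, and the 6 largest higher and 4 largest lower genes particular to each SB animal. Unnamed predicted genes and antigen receptor segments were left out of the names, not the totals. Further list members are given as examples of their list. The values of 1 gene that this rule names are not reported here.

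The steps were tested on simulated counts with 200 changed genes before use. With the spread seen between these animals the genotype test recovered 24.2% of 4-fold and 1.49% of 2-fold changes, and with the spread of the control animals alone 100% and 83.6%. Both settings gave SB and control animals the same spread, while the real SB animals differed in far more genes than the controls. The simulated rates of the genotype test may therefore not hold for the real data. The piece test in SB recovered 91.0% of 2-fold changes and that in controls 94.0%. The share of calls that were false was 15% for the genotype test, with 3 of 20 calls, 8.94% for pieces in SB and 3.93% for pieces in controls. The comparison of SB animal 1 with the other SB animals recovered 79.1% of 2-fold changes.

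Alternatives tried were each animal left out, DESeq2 1.42.0 (its size factors and its test), limma-voom, no filter and a CPM filter, single pieces, a minimum fold change, the older quasi-likelihood estimate, removal of globin and immunoglobulin genes or of X and Y genes, fits without the animal block, other distances, a correction for GC content and transcript length, and thinning of all libraries to the smallest total. GC content and length came from the annotated transcripts of the reference and were known for 99.9% of the genes in the piece test.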

Results

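Spleen RNA was sequenced from 6 mice, 2 pieces per spleen. In 3 mice, called SB animals 1 to 3, the Sleeping Beauty transposase, an enzyme that moves DNA transposons, was present with the mutagenic transposon onc2 and with VEC-Cre, a Cre recombinase used here to target the endothelium. The other 3 mice were controls given as wild type. The stated question was whether the transcriptomes of both pieces of a spleen are alike, as a reading of how clonal the whole spleen is. Libraries held 14320833 to 22031026 counts and 22268 to 23767 genes with a count. Globin RNA took 0.305% and 0.343% of counts in the pieces of SB animal 1, 3.32% and 3.83% in SB animal 2, 0.084% and 0.091% in SB animal 3, and 1.78% to 6.20% in control pieces. Immunoglobulin RNA took 0.136% to 0.837% in SB pieces and 2.23% to 3.20% in control pieces. Xist, the X-inactivation RNA of female cells, stood at 2216 CPM in SB animal 1 and 994 in SB animal 2, and at 1.66 in SB animal 3 and at most 2.46 in the controls, while the Y-linked gene Ddx3y stood at 95.5 CPM in SB animal 3, 61.2 to 76.9 in the controls, and at most 0.250 in SB animals 1 and 2. Sex-linked RNA was therefore unequal between the genotypes.

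The comparison of SB with control spleens described what distinguishes the transposon animals. Transcripts of mature B cells took a far smaller share of the RNA in all 3 SB spleens than in controls. All values are shares of a bulk library, and no cell counts were used. A fall may therefore mean fewer such cells or dilution by other cells, here and for the lists below. Cr2, the complement receptor of mature B cells (ENSMUSG00000026616, GRCm38 chromosome 1, 195136811 to 195176716), fell from 884 ± 56.0 CPM in controls to 4.07 ± 0.606 in SB (SD, n = 3 each), a log2 change of -7.73 (SE 0.24, edgeR adjusted p = 0.000312). Ms4a1, which encodes CD20, fell from 1036 ± 121 to 7.51 ± 2.05 CPM. T cell genes fell too, among them Ccr7, the homing receptor of naive lymphocytes (log2 -5.77, SE 0.19), Lef1 (log2 -5.97, SE 0.62) and Tcf7 (log2 -4.52, SE 0.48), transcription factors of T cells. Without SB animal 2 the last 2 moved to -6.58 and -5.14. Cell cycle genes rose, with Bub1b, a spindle checkpoint kinase, at 132 ± 10.8 CPM in SB against 31.8 ± 6.31 in controls (log2 2.09, SE 0.20, edgeR adjusted p = 0.00377).

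Of 17328 genes tested, 3178 were called, 1489 higher and 1689 lower in SB, and 6167 had an unadjusted p under 0.05. Of the called genes 3030 had no overlap between the 6 SB and the 6 control libraries. Among all genes tested 45.4% had animals of one genotype all above those of the other, where chance gives 10%. Of 191 immunoglobulin V genes tested, 110 fell and 0 rose by edgeR. The call count depended on which animals entered: 818, 554 and 636 genes were called without control animal 1, 2 or 3, and 6409 without SB animal 2. The balance of directions moved as well, with 241, 86 and 142 genes higher and 577, 468 and 494 lower without control animal 1, 2 or 3. The common biological coefficient of variation was 49.7%, and on simulated counts with this spread in both genotypes 24.2% of 4-fold changes were recovered.

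The largest increases among genes separated in every library were uneven between SB animals. C2cd4a, induced by inflammatory cytokines in endothelium (ENSMUSG00000047990, chromosome 9, 67830489 to 67832330), rose to 4.13, 3.76 and 33.5 CPM in SB animals 1, 2 and 3 against 2 counts in all control libraries together, a ratio of 732 with a 95% counting interval of 202 to 6046. Muc6, a gastric mucin, rose to 37.1, 4.24 and 476 CPM from 0.536 ± 0.0560 in controls. Alox5, the 5-lipoxygenase of leukotriene synthesis, rose to 62.0, 65.2 and 522 CPM from 2.25 ± 0.648, a log2 change of 6.62 (SE 1.11). Gdf3, a TGF-beta family ligand, rose by a log2 change of 6.84 (SE 0.73), and Erfe, the erythroid hormone that represses hepcidin, by 6.40 (SE 1.25). Sfrp4, Ankrd36, Espnl, Saa3 and Ugt8a completed the 10 largest increases, with log2 changes of 8.14, 7.87, 7.40, 7.27 and 6.99. Sfrp4 stood at 11.8, 3.76 and 349 CPM in SB animals 1, 2 and 3, and Espnl at 5.38, 0.421 and 37.1. Saa3 stood at 0.998, 53.6 and 8.05, and Ugt8a at 1.05, 3.73 and 58.5. Without SB animal 3 the log2 change was 7.37 for C2cd4a, 5.30 for Muc6, 4.20 for Sfrp4, 5.12 for Espnl, 3.86 for Ugt8a and 4.86 for Alox5. Without SB animal 2 it was 5.07 for Saa3 and 5.19 for Erfe, and without control animal 1 it was 7.25 for Erfe and 8.52 for Ankrd36. C2cd4a and Gdf3 were called with each animal left out. Ankrd36 was not called without control animal 2 or 3. Muc6, Sfrp4, Espnl, Saa3, Ugt8a, Alox5 and Erfe were not called without any 1 of the 3 controls (edgeR adjusted p up to 0.172). The 10 largest decreases were called with each animal left out and were led by H2-Ea-ps, a class II histocompatibility pseudogene (log2 -9.06, SE 0.38), H2-Q1, a class I gene of the same complex (log2 -7.96, SE 0.93), and Il5ra, the interleukin 5 receptor (log2 -7.88, SE 0.42). Fcer2a, Cr2, Dtx1, Fcamr, Ms4a1 and Fcmr, all with known expression in B cells, followed at log2 -7.79, -7.73, -7.20, -7.16, -7.08 and -7.04. Rps13-ps1 (log2 -7.53, SE 0.69) is a processed pseudogene, and H2 genes and pseudogenes may share reads with their near copies, so these values are uncertain. Rps13-ps1 was near absent in SB animals 1, 2 and 3 (0.0555, 0.271 and 0.0482 CPM) against 23.5 ± 1.49 CPM in controls. Strain and genotype are confounded at H2-Ea-ps, as described further below, so its decrease cannot be assigned to the SB genotype. Whether the same holds for H2-Q1 and Rps13-ps1 is open. Without SB animal 2 the log2 change was -9.80 for H2-Q1, -8.70 for Rps13-ps1 and -7.75 for Fcamr. Of 86 named genotype genes called, 28 were called with each animal left out.

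Lymphoid lists fell. In the B cell list 20 of 22 genes fell and 2 did not pass, and 20 fell when adjusted over the list alone, with Pax5 at log2 -6.74 and Cd79a at log2 -6.61 (camera adjusted p = 1.6e-22, adjusted p = 0.518 with an estimated correlation). The B cell median log2 change was -6.46, -6.19 and -6.69 in SB animals 1, 2 and 3. In the T cell list 15 of 25 fell and 10 did not pass, and 19 fell adjusted over the list alone (camera adjusted p = 2.39e-11, adjusted p = 0.647 with an estimated correlation). Its median log2 change was -4.96, -2.53 and -5.41 in SB animals 1, 2 and 3. Cd4 RNA, which macrophages can also carry, stood at 279 CPM in SB animal 2, 6.85 and 9.94 in SB animals 1 and 3, and 122 ± 8.61 in controls, and did not pass. In the NK cell list 2 of 14 fell, Klri2 (log2 -5.91) and Txk (log2 -3.99), as did 2 adjusted over the list alone (camera adjusted p = 0.00308, adjusted p = 0.682 with an estimated correlation). Without SB animal 2 these moved to -7.50 and -5.18, without SB animal 3 Klri2 moved to -5.29, and Txk was called in 3 of 6 fits with an animal left out. The NK cell median log2 change was -3.53, -0.43 and -4.44 in SB animals 1, 2 and 3, so it was small in SB animal 2. In the plasma cell list 3 of 13 fell, Mzb1 (log2 -4.26), Irf4 (log2 -3.72) and Igha (log2 -3.91), and 5 adjusted over the list alone (camera adjusted p = 0.00156, adjusted p = 0.682 with an estimated correlation). In SB animals 1, 2 and 3 Mzb1 stood at 4.46, 28.4 and 5.55 CPM, Irf4 at 2.94, 25.7 and 4.05, and Igha at 28.1, 103 and 355. Without SB animal 2 the log2 change was -5.60 for Mzb1 and -5.35 for Irf4, and without SB animal 3 it was -5.21 for Igha. They were called in 3, 1 and 2 of 6 fits with an animal left out. In the dendritic list 5 of 16 fell, including Cd209a (log2 -4.29) and Ccr9 (log2 -3.34), and 5 adjusted over the list alone (camera adjusted p = 1.78e-05, adjusted p = 0.647 with an estimated correlation). Cd209a moved to -5.95 without SB animal 2 and was called in 2 of 6 fits with an animal left out. Ly6d, a further member, is also a B cell gene. In the stroma list 5 of 21 fell and 2 rose, and 7 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00308, adjusted p = 0.700 with an estimated correlation). The members that fell included Ccl21a (log2 -5.69), Ccl19 (log2 -5.31) and Cxcl13 (log2 -4.17), chemokines that position lymphocytes in white pulp, while Sparc, a matrix protein, rose by 1.16.

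Camera with the preset correlation called the proliferation, erythroid, heme synthesis and megakaryocyte lists higher in SB. In the proliferation list 25 of 30 genes rose, 5 did not pass, and 30 rose adjusted over the list alone (camera adjusted p = 8.51e-17, adjusted p = 0.647 with an estimated correlation). Mcm5 and Mcm2, subunits of the replicative helicase, rose by log2 changes of 1.55 (SE 0.17) and 1.86 (SE 0.23), and Tyms, thymidylate synthase, by 2.30 (SE 0.26). In the erythroid list 9 of 30 rose and 21 did not pass, and 16 rose adjusted over the list alone (camera adjusted p = 0.000187, adjusted p = 0.682 with an estimated correlation). Tal1, a transcription factor of erythroid and megakaryocytic cells, rose from 47.8 ± 24.1 to 540 ± 141 CPM, and Nfe2, Rhag, Gata1 and Epor rose by log2 changes of 3.16, 3.31, 2.58 and 2.51. The adult globin Hbb-bs did not pass (8697 ± 13404 CPM in SB, 26919 ± 9343 in controls, log2 -1.60, SE 1.37). In heme synthesis 2 of 12 rose, Cpox (log2 2.99) and Alad (log2 2.09), and 3 adjusted over the list alone (camera adjusted p = 0.0326, adjusted p = 0.719 with an estimated correlation). Cpox moved to 2.35 without SB animal 2, and Cpox and Alad were called in 2 and 3 of 6 fits with an animal left out. In the megakaryocyte list 6 of 20 rose and 14 did not pass, and 11 rose adjusted over the list alone (camera adjusted p = 0.00649, adjusted p = 0.647 with an estimated correlation). Itga2b, the platelet integrin subunit CD41, stood at 2275, 250 and 3176 CPM in SB animals 1, 2 and 3 against 132 ± 48.2 in controls, and Pf4, platelet factor 4, rose by 2.53 (SE 0.58). Pf4 moved to 1.90 without SB animal 3, and Itga2b and Pf4 were called in 1 and 2 of 6 fits with an animal left out. The list medians in SB animals 1, 2 and 3 were 0.40, 2.98 and 2.19 for erythroid, 0.29, 1.96 and 0.64 for heme synthesis, and 1.45, 1.21 and 1.29 for megakaryocyte genes. Fry, which tests whether a list moves one way and does not compare it with other genes, called the B cell, T cell, plasma cell, dendritic, proliferation and adipose lists. It did not call the erythroid (adjusted p = 0.181), heme synthesis (adjusted p = 0.358) or megakaryocyte list (adjusted p = 0.0796). Nor did fry call the NK cell (adjusted p = 0.0870) or stroma list (adjusted p = 0.0796), which camera called lower.

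Myeloid lists did not pass camera and differed between SB animals. In the primary granule list 5 of 12 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.173). Those that rose included Ms4a3 (log2 4.61), Ctsg (log2 4.04) and Mpo (log2 3.22), genes of promyelocytes. Without control animal 1 the log2 change was 5.64 for Ms4a3, 5.05 for Ctsg and 4.01 for Mpo, and without SB animal 1 it was 3.64 for Ms4a3. Ms4a3, Ctsg and Mpo were called in 3, 4 and 3 of 6 fits with an animal left out. In the mature neutrophil list 3 of 22 rose, Padi4, Anxa1 and Stfa2l1, and 5 adjusted over the list alone (camera adjusted p = 0.0603), with median log2 changes of -0.996, 3.16 and 1.85 in SB animals 1, 2 and 3. Padi4 moved from 3.51 to 2.43 without SB animal 1. In the monocyte list F13a1 rose (log2 5.32) and Ace fell (log2 -1.57), 14 of 16 did not pass, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.953). Its median and mean, 1.23 and 1.09, were positive where camera pointed down. F13a1 stood at 133, 916 and 78.5 CPM in SB animals 1, 2 and 3, moved to a log2 change of 3.50 without SB animal 2, and was called in 3 of 6 fits with an animal left out. In the red pulp macrophage list Mrc1 rose (log2 3.60) and 17 of 18 did not pass in the edgeR test over all genes, and 0 passed adjusted over the list alone (camera adjusted p = 0.755). Its medians were -1.58, 2.65 and -0.18 in SB animals 1, 2 and 3, and without SB animal 2 camera called it lower (adjusted p = 0.045). Mrc1 stood at 679, 1812 and 111 CPM in SB animals 1, 2 and 3, with SB libraries that overlapped the controls. Its log2 change was 2.47 without SB animal 2, and it was called in 1 of 6 fits with an animal left out. In the marginal zone list 1 of 6 fell, Cd209d, as it did adjusted over the list alone (camera adjusted p = 0.535), and camera pointed down where median and mean were 0.91 and 0.73. Cd209d moved from -4.13 to -6.08 without SB animal 2 and was called in 2 of 6 fits with an animal left out. In the mast and basophil list Gata2 rose (log2 4.07), Cma1 fell (log2 -2.60) and 8 of 10 did not pass, with 1 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.960, pointing down against a median of 0.55 and a mean of 1.18). Without SB animal 1 Cma1 moved to -3.34 and Gata2 to 2.63, and Gata2 was called in 1 of 6 fits with an animal left out. In the eosinophil list Il5ra fell and 7 of 8 did not pass, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.740, pointing down, median 0.93, mean -0.36).

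Among the remaining lists, Cdh5, which encodes VE-cadherin (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511), stood at 51.9, 47.5 and 176 CPM in SB animals 1, 2 and 3 against 35.8 ± 2.68 in controls and did not pass (log2 1.39, SE 0.53, edgeR adjusted p = 0.123). Without SB animal 3 its log2 change was 0.51. In the endothelial list 3 of 22 rose, among them Stab2, a sinusoidal scavenger receptor (log2 1.09, SE 0.15), and Eng, endoglin (log2 1.36, SE 0.20), while Pecam1 (log2 -1.16, SE 0.18) and Madcam1 fell. Adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.0679). Pi4ka, the lipid kinase named in the series title (ENSMUSG00000041720, chromosome 16, 17280351 to 17406314), stood at 117 ± 20.4 CPM in SB and 136 ± 5.34 in controls (log2 -0.19, SE 0.17, edgeR adjusted p = 0.456). In the phosphoinositide kinase list 2 of 19 rose, Pip5k1b (log2 1.97) and Pik3cb (log2 1.48), and 2 fell, Efr3b (log2 -2.17) and Pik3ca (log2 -0.59), with 2 rising and 3 falling adjusted over the list alone (camera adjusted p = 0.960). In the stem and progenitor list 5 of 22 rose, including Tal1, Lmo2 (log2 0.88) and Gata2, and Mecom fell (log2 -1.50), with 6 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.245). In the list of blood regulators and oncogenes 8 of 40 rose, including Ezh2, a histone methyltransferase (133 ± 2.89 CPM in SB, 58.9 ± 8.59 in controls), and Runx1 (log2 0.83, SE 0.17), and 2 fell, among them Ikzf1 (log2 -0.85, SE 0.15), as 8 and 2 did adjusted over the list alone (camera adjusted p = 0.122).

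Lists for handling, interferon response, neighbouring tissue and sex held few called genes. In the immediate early list Fos rose (log2 2.19), Zfp36 fell (log2 -1.82), and 11 of 13 did not pass, as adjusted over the list alone, where 1 rose and 1 fell (camera adjusted p = 0.683). In the interferon list Oas1a rose (log2 2.19) and 19 of 20 did not pass, with 1 rising adjusted over the list alone (camera adjusted p = 0.683) and medians of -1.37, 1.91 and 0.39 in SB animals 1, 2 and 3. In the adipose list 1 of 4 tested genes rose, Fabp4, which endothelium and macrophages also express, and the same number adjusted over the list alone (camera adjusted p = 0.278). The pancreas list had 2 tested genes and the list of embryonic globin and fetal genes 2, and in each 0 were called by edgeR, with 0 and 1 adjusted over the list alone. The liver list had 1 tested gene, Serpina1b, which fell (log2 -5.02, SE 0.59), as it did adjusted over the list alone. In the sex list Xist rose (log2 9.01, SE 2.31, edgeR adjusted p = 0.0459) and 4 Y-linked genes did not pass, with 1 rising adjusted over the list alone (camera adjusted p = 0.205, pointing down with a median of -1.08 and a mean of 1.01). Xist moved to 7.89 without SB animal 1 and was called in 1 of 6 fits with an animal left out.

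**Figure D1:**
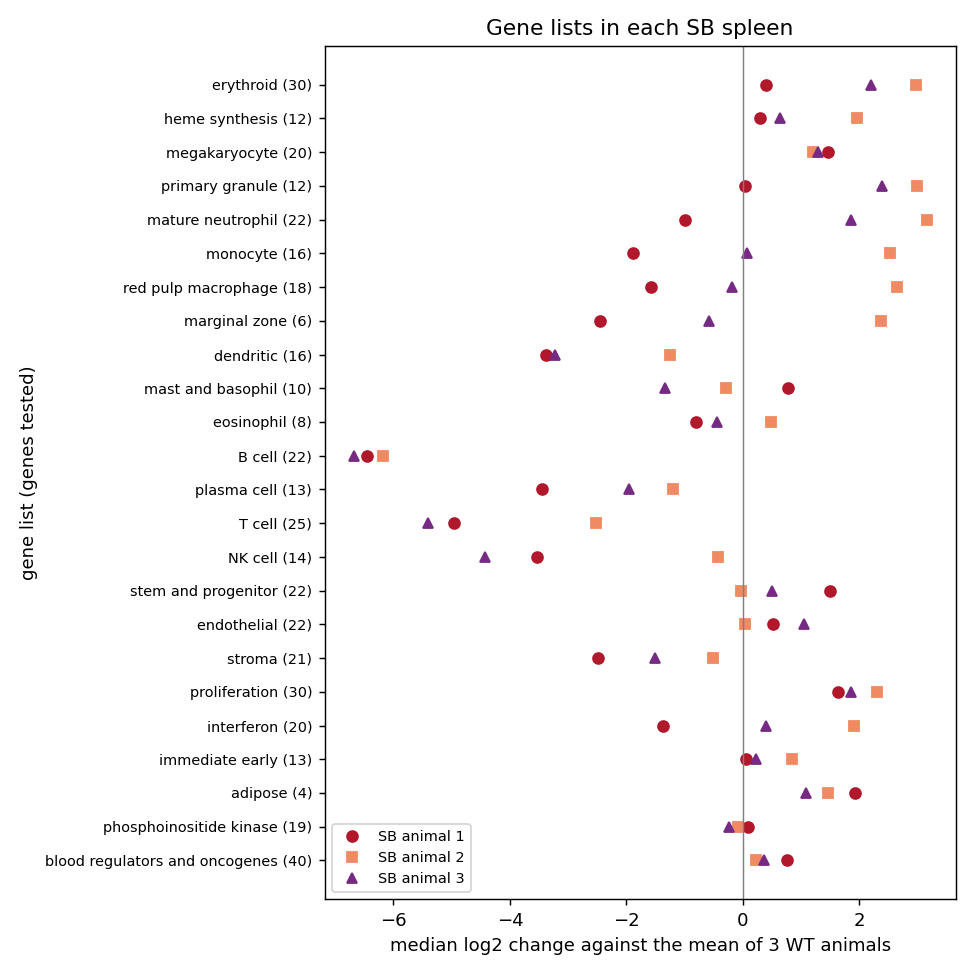
Median log2 change of each gene list in SB animals 1, 2 and 3 against the mean of the 3 control animals, with the number of genes tested in brackets. The B cell medians of the 3 animals lie together at -6.46, -6.19 and -6.69, and those of the red pulp macrophage list lie apart at -1.58, 2.65 and -0.18.

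The comparison of piece 2 with piece 1 asked whether parts of a spleen differ in a repeated way. In controls, some single genes were higher in piece 2, among them Plvap and Lrg1 of vessels and Tnxb of matrix. Plvap, a protein of fenestrated endothelium, rose from 105, 115 and 104 CPM in piece 1 to 168, 210 and 192 CPM in piece 2 of control animals 1, 2 and 3 (log2 0.81, SE 0.07, edgeR adjusted p = 0.00185). Lrg1, a secreted vascular glycoprotein, rose by 1.09 (SE 0.10), and Tnxb, a matrix protein, by 1.43 (SE 0.14). Dmpk rose by 0.96 (SE 0.10), and Hba-ps4, an alpha globin pseudogene that may share reads with its parent genes, by 1.84 (SE 0.20). Cnr2, the cannabinoid receptor of B cells, fell by 0.48 on the log2 scale (SE 0.07), and Plac8, Eif3e, Ptp4a2 and Prps2 fell by 0.46, 0.48, 0.46 and 0.52.

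In the controls 1514 of 15523 genes were called between pieces, 1004 higher and 510 lower in piece 2. In the erythroid list 27 of 30 genes rose in piece 2, and 30 adjusted over the list alone, with list medians of 0.33, 1.41 and 1.32 in control animals 1, 2 and 3. Of the red pulp macrophage list 15 of 18 rose and 1 fell, of heme synthesis 10 of 12 rose, of proliferation 14 of 30 rose, and of the endothelial list 10 of 22 rose, with 16 rising and 1 falling, 11, 20 and 12 rising adjusted over each list alone. Of the mature neutrophil list 7 of 21 rose, with a median of 0.83, of NK cell genes 3 of 14 and of megakaryocyte genes 2 of 20, with 12 rising and 1 falling, 4 rising, and 6 rising and 1 falling adjusted over each list alone. Of the stroma list 4 of 20 rose and 1 fell, with a median of 0.05, and 7 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.796). Of the T cell list 0 of 25 were called by edgeR, with a median of -0.13. Of the B cell list 4 of 22 fell, and 6 adjusted over the list alone, with a median of -0.22. Camera adjusted p was 2.44e-22 for erythroid, 2.67e-09 for heme synthesis, 1.5e-12 for red pulp macrophage, 9.42e-06 for endothelial and, pointing down, 1.56e-06 for B cell genes, and adjusted p = 0.448 with an estimated correlation for each of these. It was 9.93e-10 for proliferation and 0.00198 for NK cell genes (adjusted p = 0.518 with an estimated correlation for both). For mature neutrophil genes it was 0.000167 (adjusted p = 0.575 with an estimated correlation). It was 0.00168 for megakaryocyte and, pointing down, 0.00215 for T cell genes (adjusted p = 0.637 with an estimated correlation for both). The number of calls was 0 without control animal 2 or without control animal 3 by edgeR, where 2443 and 2818 genes had an unadjusted p under 0.05. It was 3319 and 895 without SB animal 1 and SB animal 3, which share the estimate of spread. The balance of directions moved too. Without SB animal 1 the calls were 1667 higher and 1652 lower in piece 2, and without control animal 1 866 higher and 193 lower.

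In SB spleens 1 gene passed by edgeR, Prkg1, a cyclic GMP-dependent kinase, at 48.4 and 11.9 CPM in pieces 1 and 2 of SB animal 1, 1.88 and 0.866 in SB animal 2, and 0.614 and 0.345 in SB animal 3 (log2 -1.82, SE 0.21, adjusted p = 0.0486). An unadjusted p under 0.05 was found by edgeR for 3408 genes in SB and 4355 in controls. The median absolute log2 change over all genes was 0.160 in SB and 0.176 in controls. The counts of 1 and 1514 calls therefore overstate how far the genotypes differ in this comparison. In SB limma-voom also called 1 gene. In each of the 28 lists 0 genes were called in SB by edgeR, and the erythroid medians were -0.17, 0.03 and 0.04 in SB animals 1, 2 and 3. Without SB animal 2 the count was 709 with Prkg1 among them, without SB animal 1 it was 4 without Prkg1, and it was 0 without SB animal 3 or any 1 of the controls, where 2504 to 3212 genes had an unadjusted p under 0.05. The piece difference itself differed between genotypes for 212 genes, 41 of them with a more positive and 171 with a more negative difference in SB, among them 8 of 18 red pulp macrophage genes, 5 of 22 endothelial genes and 1 of 30 erythroid genes, all more negative in SB. So were 2 of 12 heme synthesis, 2 of 20 stroma, 2 of 30 proliferation and 1 of 6 eosinophil genes, while 2 of 16 monocyte and 1 of 12 primary granule genes were more positive in SB. The number of genes whose piece difference differed between genotypes was 0 without SB animal 3, without control animal 2 or without control animal 3, where 1863 to 2181 genes had an unadjusted p under 0.05, and 355 and 544 without SB animal 1 and control animal 1.

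Across all 6 animals 474 genes were called, 200 higher and 274 lower in piece 2. This count and that of the difference between genotypes rest on matching control sections A and B to SB pieces 1 and 2. With the pieces of all 3 controls exchanged, the edgeR counts were 0 over all animals and 1878 for the difference. Kcnq1ot1, an antisense RNA of the imprinted Kcnq1 locus whose reads cannot be told from those of the overlapping gene, rose by 0.77 (SE 0.10, edgeR adjusted p = 0.0241), and Snrnp70, a U1 splicing factor, by 0.45 (SE 0.06), in 6 of 6 animals each. Safb, AI480526 and Rbm4b rose by 0.38, 0.64 and 0.59. Lypla1, an acyl-protein thioesterase, fell by 0.52 (SE 0.07), and St8sia4, Tmed7, Sp3 and Gpr174 fell by 0.43, 0.45, 0.50 and 0.51, each in 6 of 6 animals. With a correction for GC content and transcript length, chosen after the data were seen, 47 genes were called, 44 of them among the 474. An unadjusted edgeR p under 0.05 was found for 3394 genes with the correction and 3888 without it. Of these 47 genes 33 were higher and 14 lower in piece 2, so the balance of directions turned round. The count was 0 without SB animal 3 or without any 1 of the 3 control animals by edgeR, where 2975 to 3562 genes had an unadjusted p under 0.05.

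**Figure D2:**
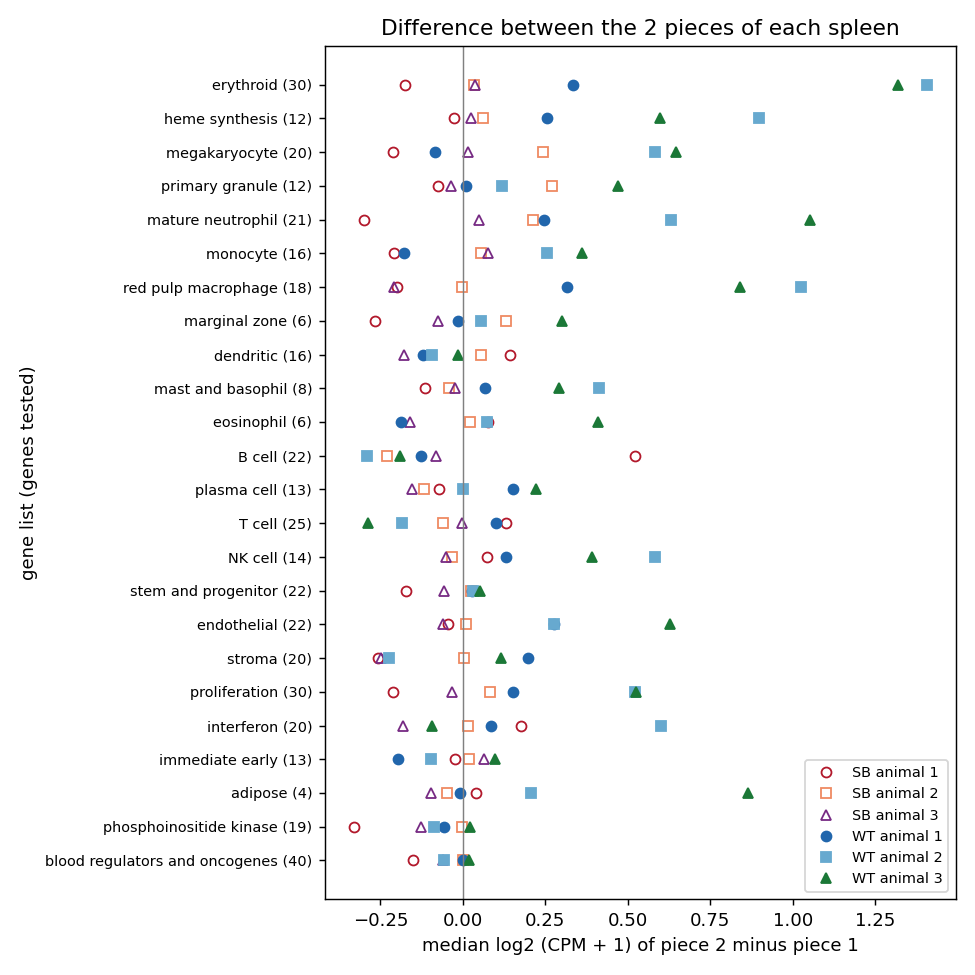
Median difference of piece 2 minus piece 1 per gene list and animal, in log2(CPM + 1), with the number of genes tested in brackets and open symbols for SB animals, filled for controls (WT). The erythroid medians of control animals 1, 2 and 3 lie at 0.33, 1.41 and 1.32 and those of SB animals at -0.17, 0.03 and 0.04.

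The comparison between animals of one genotype asked how far spleens of different SB animals stand apart. Each SB spleen carried its own set of highly expressed genes in both of its pieces. In SB animal 1, Rab3b, a vesicle-trafficking GTPase, stood at 1381 and 1553 CPM in pieces 1 and 2 against at most 4.59 in any other library, and Npy, neuropeptide Y, at 184.7 and 261.9 CPM against at most 6.52. In SB animal 2, Cbr2, a carbonyl reductase, stood at 256 and 284 CPM against at most 1.46, and Pla2g2f, a secreted phospholipase, at 283 and 173 CPM against at most 2.15. In SB animal 3, Car6, a secreted carbonic anhydrase, stood at 1169 and 1390 CPM against at most 2.53, and Nmnat2, an NAD synthesis enzyme, at 496 and 498 CPM against at most 3.84.

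Of 15523 genes, 11323 (72.9%) differed among the 3 SB animals by the edgeR F test and 73 (0.470%) among the 3 controls, where 1060 had an unadjusted p under 0.05. These p-values measure only the spread between pieces of one spleen. Genes particular to 1 animal numbered 4659 for SB animal 1 (2249 higher, 2410 lower), 4024 for SB animal 2 (2325 higher, 1699 lower) and 3642 for SB animal 3 (1961 higher, 1681 lower), and 17, 7 and 30 for control animals 1, 2 and 3. The Fisher tests of lists given for single animals count genes as independent, while the members of a list vary together (estimated correlation 0.878 for red pulp macrophage, 0.823 for interferon, 0.845 for heme synthesis and 0.648 for erythroid genes). Their p-values are therefore too small and describe these animals only.

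SB animal 1 was further set apart by higher Ovol1, Krt18, Mfsd2a and Scin (log2 9.45, 8.87, 8.79 and 8.61 against the other SB animals). Ccnb1ip1, a cyclin B1-interacting protein, had 0 counts in both pieces, at least 154-fold below the other SB animals at a floor of 3 counts over both pieces. Itgb2l had 3 counts, a ratio of 158 with a 95% counting interval of 53.9 to 767, and Ank2 and Ccl2 were lower by log2 -7.04 and -6.50. These 3 genes and Ccnb1ip1 lay above all controls in SB animals 2 and 3, and Krt18 below all controls there, so their changes rest in part on those animals. Of the stem and progenitor list 10 of 22 genes were particular to this animal and higher, including Kit (166 CPM, controls 42.1 ± 4.57) and Myb (377 CPM, controls 51.4 ± 3.80) (Fisher's exact test, one-sided, adjusted p = 0.00408), as were 16 of 40 blood regulators and oncogenes (adjusted p = 0.000738). Lower and particular were 13 of 18 red pulp macrophage genes (Fisher's exact test, adjusted p = 6.03e-06), 10 of 16 monocyte genes (adjusted p = 0.000726) and 11 of 20 stroma genes (adjusted p = 0.00111).

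SB animal 2 was set apart by macrophage, interferon and erythroid genes. Higher and particular to it were 16 of 18 red pulp macrophage genes (Fisher's exact test, one-sided, adjusted p = 5.83e-10), such as Hmox1, heme oxygenase 1, at 1089 CPM against 389 ± 39.8 in controls, 16 of 20 interferon genes (adjusted p = 6.83e-09), 11 of 12 heme synthesis genes (adjusted p = 2.42e-07), 17 of 30 erythroid genes (adjusted p = 2.58e-06) and 14 of 21 mature neutrophil genes (adjusted p = 2.37e-06). The same held for 11 of 16 monocyte genes (Fisher's exact test, adjusted p = 2.45e-05), 15 of 30 proliferation genes (adjusted p = 8.12e-05) and 4 of 6 marginal zone genes (adjusted p = 0.0446). Its named genes also included higher Ifi202b, Rtn1, Mmp13 and Cxcl9 (log2 9.04, 7.61, 7.43 and 7.33 against the other SB animals) and lower Eya2, Itih5 and Nrgn (log2 -6.02, -5.12 and -5.04). Ifi202b, Rtn1 and Cxcl9 lay below all controls in SB animals 1 and 3, and Eya2, Itih5 and Nrgn above all controls there, so these changes rest in part on those animals. Tacr1 had 3 counts, a ratio of 828 with a 95% counting interval of 283 to 4015 that is carried by SB animal 3 (134 and 136 CPM), while SB animal 1 held 3.03 and 3.44 CPM.

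SB animal 3 was set apart by endothelial genes, of which 10 of 22 were particular and higher (Fisher's exact test, one-sided, adjusted p = 0.00144), including Cdh5, Kdr (125 CPM, controls 42.1 ± 2.60) and Plvap (338 CPM, controls 149 ± 12.9). Lower and particular were 10 of 14 NK cell genes (Fisher's exact test, adjusted p = 6.03e-06), 10 of 25 T cell genes (adjusted p = 0.00256) and 12 of 40 blood regulators and oncogenes (adjusted p = 0.0108). Trabd2b, Tacr1 and Kcng1 were higher by log2 8.89, 7.89 and 7.66, and Cdh22, with 3 counts in the other SB animals together, by a ratio of 231 (95% counting interval 78.4 to 1123). Kcng1 and Cdh22 lay below all controls in SB animals 1 and 2, so their changes rest in part on those animals. Pls1 stood at 0.283 and 0.247 CPM against at least 3.69 in any other library. Its log2 change of -7.43 is against the other SB animals, with 210 and 150 CPM in SB animal 1 and 11.6 and 12.2 in SB animal 2. Both animals lay above all controls, so this change rests in part on them. Rab3b stood at 0.614 and 0.690 CPM, against 2.53 and 4.59 in SB animal 2, so its log2 change of -6.82 mostly restates the high values of SB animal 1. Itln1 had 1 count in this animal, a ratio of 796 (95% counting interval 143 to 31472), with 16.5 and 48.5 CPM in SB animal 1 and 5.85 and 6.98 in SB animal 2. Ifi202b had 0 counts, at least 394-fold below the other SB animals together at a floor of 3 counts over both pieces. That bound is carried by SB animal 2, as SB animal 1 held 1.77 and 1.47 CPM.

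Distances between libraries put the pieces of each SB spleen next to each other. Over the 500 most variable genes the 2 pieces lay 0.833, 0.571 and 0.685 log2 units apart in SB animals 1, 2 and 3 (mean 0.696 ± 0.131, SD, n = 3), while pieces of different SB animals lay 3.32 apart on average (3.05 to 3.53). In controls the pieces of one spleen lay 0.442, 0.674 and 0.659 apart (mean 0.592 ± 0.130) and pieces of different animals 0.733 on average (0.569 to 0.902). SB and control libraries lay 4.81 apart on average. Each SB piece had the other piece of its own spleen as its nearest library. In the controls piece 1 of animal 2 and piece 1 of animal 3 were nearest to each other, and piece 2 of animal 2 was nearest to piece 2 of animal 1.

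Pieces of one spleen were nearer than other pairings in both genotypes together (exact permutation over 225 pairings, one-sided p = 0.00889). Within a genotype 15 pairings allow no p below 0.0667, which SB reached (exact one-sided p = 0.0667) and controls did not (exact one-sided p = 0.133). The same-spleen distance was 0.105 larger in SB than in controls, within the spread between animals (exact permutation of 20 assignments, two-sided p = 0.4, smallest possible 0.1). Over all filtered genes pieces of one spleen lay 0.428 apart in SB and pieces of different SB animals 1.48 (exact one-sided p = 0.0667). In controls these distances were 0.456 and 0.467, a ratio of 1.03 (exact one-sided p = 0.333).

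**Figure D3:**
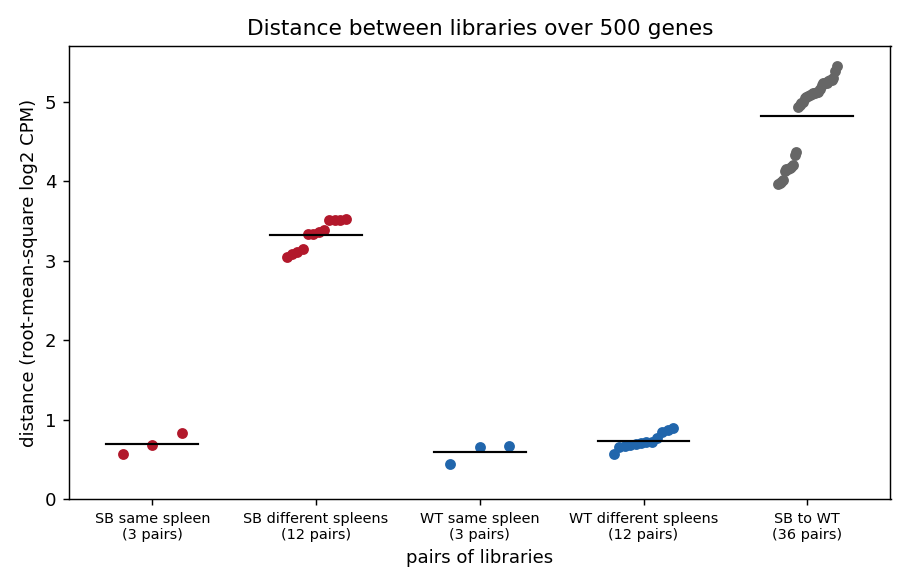
Distance between pairs of libraries in root-mean-square log2 CPM over the 500 most variable genes, 1 point per pair with the mean as a bar. The same-spleen pairs of both genotypes lie at 0.442 to 0.833, while pairs of different SB animals lie at 3.05 to 3.53.

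Immunoglobulin V gene usage gave a reading of the diversity of V gene RNA, from few counts in SB. In SB animals 1, 2 and 3 the median log2 change was -6.46, -6.19 and -6.69 for the B cell list. For the plasma cell list it was -3.45, -1.20 and -1.95. V counts of SB and controls may therefore come from different mixes of B cells and plasma cells, which was not tested. The effective number of heavy chain V genes was 27.1 ± 8.79 in SB and 40.0 ± 5.12 in controls, and of kappa V genes 21.3 ± 3.42 and 38.4 ± 2.92 (SD, n = 3, exact permutation, two-sided p = 0.1 for each, the smallest possible). For lambda it was 1.95 ± 0.905 and 2.39 ± 0.262 (exact permutation, two-sided p = 0.5). SB animal 2 used Ighv1-9 for 17.2% (95% interval 16.2 to 18.2) and 14.7% (13.9 to 15.6) of heavy chain V counts in its pieces, and Iglv1 for 97.5% (96.8 to 98.1) and 98.3% (97.9 to 98.7) of lambda V counts, against 43.1% to 62.2% in control pieces. The most used heavy chain V gene was the same in both pieces of 1 of 3 SB and 2 of 3 control spleens, and the most used kappa V gene in 1 of 3 and 3 of 3. Heavy chain V counts numbered 564 to 6994 per SB piece and 16686 to 29650 per control piece, and V genes of one family may share reads.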

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

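The tests of sex, of more red pulp in piece 2 and of both explanations for H2-Ea-ps were chosen only after the result was seen, as were the corrections for GC content, length and depth as settings. Their outcomes are hypotheses about these samples.

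Groups of 6 libraries, 2 pieces from each of 3 spleens, were searched for a single library far from the others. Chance gives about 1 in 20 such groups only for independent libraries, and pieces of one spleen are not independent. The number found therefore cannot be compared with that rate. Among 306 groups, 8 held a single library far from the others. In SB these were Rps13-ps1 in piece 1 of animal 2 (0.578 CPM), Pecam1 (189 CPM), Mcm5 (346 CPM) and Prkg1 (48.4 CPM) in piece 1 of animal 1, and Itln1 in piece 2 of animal 1 (48.5 CPM). In controls these were Dtx1 in piece 2 of animal 2 (302 CPM), and in piece 2 of animal 3 the share of the most used kappa V gene (11.6%) and the effective number of kappa V genes (31.1).

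The difference between pieces was itself different between genotypes for 212 genes by the test of that difference (edgeR adjusted p = 0.0372 for each gene named here). The change from piece 1 to piece 2 was more positive in SB than in controls for Grap (0.68), Prkdc (0.68), Plac8 (0.60), Capg (0.60) and Ctla2a (0.78). It was more negative in SB for Sema3d (-2.03), Plvap (-0.79), Lrg1 (-0.97), Pcdh12 (-1.66) and Tnxb (-1.45), all log2. These values compare changes between pieces, not levels in piece 2. Of 32 ways to swap the pieces within animals, 2 gave as many genes, the real one and an exchange of the pieces of all 3 controls with 1878, so chance is not excluded by this count of swaps. That exchange turns the difference between genotypes into their sum and points to a structure of the samples, and the highest of the remaining swaps gave 65 genes.

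The SB spleens differed from each other in 11323 genes. Sex could have set them apart, but SB animals 1 and 2, which both carry Xist RNA, lay 3.56 apart over autosomal genes, above the 0.916 that was the largest distance between different controls. Depth and a few abundant genes were also argued against, with 11008 genes after thinning to the smallest total and 11235 without globin and immunoglobulin genes. The differences may be biological, and separate transposon insertions in each animal are a possible source. Insertions, segments of another strain, age and disease stage were not analysed for the SB animals and remain open.

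In control spleens 1514 genes differed between pieces. GC content and length were argued against for the erythroid part, since 24 of 30 erythroid genes were still called after the correction, and depth by 1469 genes after thinning. More red pulp in piece 2 stays open, because the erythroid, red pulp macrophage and endothelial medians, which lay above the B cell median in 3 of 3 controls, are the values that prompted it, and the position of each piece in the spleen is not given in the sources used here. For the 474 genes called over all animals the same correction left 47, so GC content and transcript length may cause part of that count. Genes with an unadjusted edgeR p under 0.05 went only from 3888 to 3394. Much of the fall in calls may therefore be genes that lay near the adjusted threshold. The 10 named genes still passed, with Kcnq1ot1 moving from 0.77 (SE 0.10) to 0.57 (SE 0.09) and Lypla1 from -0.52 (SE 0.07) to -0.40 (SE 0.07), while Rbm4b moved away from 0, from 0.59 to 0.72, and why single calls ended was not tested.

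H2-Ea-ps held 18 counts in all SB libraries and 8936 in all controls. In SB animal 2 H2-Aa and Cd74 lay at log2 -0.30 and -0.02 relative to controls. H2-Ea-ps lay -8.16 from the median change of 4 class II genes, which argues against loss of class II expressing cells in that animal. In SB animals 1 and 3 class II RNA fell as well, with H2-Aa at 60.8 to 78.2 and 64.8 to 66.9 CPM against 4485 to 6463 in controls. Loss of such cells may therefore add to the decrease there. H2-Ea-ps stood at 0.148 to 0.804 per 1000 class II counts in these 2 animals, from 1 to 5 counts per library, against 4.17 to 5.18 in controls. A strain variant may be the cause, since the b haplotype of C57BL/6, the strain given for all animals, is known to make no transcript of this gene. Of 16 genes near absent in SB (under 0.5 CPM) and present in controls (above 5 CPM), 2 lay in the H2 region, H2-Ea-ps and H2-Q1, and without H2-Ea-ps itself the excess was not past the threshold (Fisher's exact test, one-sided p = 0.127). Each control library held 1267 to 1765 counts of H2-Ea-ps, which the b haplotype would not give. This argues against the controls carrying that haplotype at this gene, so strain and genotype are confounded there. How far such a difference extends beyond H2-Ea-ps is open, because 1 further gene is too few to decide.

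Other splits of the samples bear on the counts as follows. For the genotype comparison 1 of 10 splits, the real one, gave 3178 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05. For gene lists 6 of 10 splits gave at least the 10 real calls, the highest other 15. Groupings that mix SB and control animals thus gave as many list calls as the genotypes did. The number of lists called by camera at the preset correlation therefore does not set the genotypes apart from other groupings. For pieces over all animals 1 of 32 swaps, the real one, gave 474 genes and the highest other 0. That share is under 0.05, but the count of 474 fell to 0 without SB animal 3 or without any 1 control. For pieces in SB 2 of 4 swaps gave at least the real 1 gene, the highest other 3, and for pieces in controls 1 of 4, the real one, gave 1514, the highest other 0, and 4 swaps are too few for either.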

How the results depend on the processing

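The corrections for GC content and length, the thinning, and the fits without X and Y genes, without globin and immunoglobulin genes for the animal tests, or without piece 2 of SB animal 1 were chosen only after the result was seen. The cause was not tested for any change given here. Genotype calls rose to 5631 with DESeq2 and fell to 1751 with a minimum change of 1.5-fold, and ranged from 554 to 6409 with each animal left out. Of 86 named genotype genes called, 28 were called in all alternatives that gave them a value, and 0 changed direction. List calls were 0 with an estimated correlation, 6 with fry and 9 to 12 with each animal left out. For red pulp macrophage, camera reversed to lower without SB animal 2 (adjusted p = 0.045, range 0.045 to 0.865 with each animal left out, against 0.755 with all animals). Without the animal block the piece comparison called 0 genes in all animals, in SB, in controls and for the difference between genotypes by edgeR, with 576, 312, 395 and 197 at an unadjusted p under 0.05. Over all animals limma-voom called 799 genes between pieces and the GC and length correction with the block 47. In SB the count was 14 with no filter, 0 with the GC and length correction and 0 after thinning, both with the block. With each animal left out the counts ranged from 0 to 413 over all animals, 0 to 709 in SB, 0 to 3319 in controls and 0 to 544 for the difference. Genes that differed among controls numbered 144 with no filter, 33 with the spread of the controls alone and 33 without globin and immunoglobulin genes. The larger same-spleen distance in SB reversed with all filtered genes (-0.0281) and with 1 minus Spearman correlation (-0.00284), without SB animal 1 (-0.00724) and without control animal 1 (-0.0273), and ranged from -0.0273 to 0.175 with each animal left out. Its exact two-sided p lay between 0.1 and 1 over all alternatives. The exact one-sided p for both genotypes was 0.0222 to 0.0444 with each animal left out, where fewer pairings exist. Direction and side of the threshold were kept in 100 values of the planned results, 243 of gene lists, 1397 of named genotype genes, 243 of named piece genes and 188 of named animal genes, while 39 planned counts or values without a test moved beyond the limit set for them. A call was lost, with its direction kept, in 18 values of lists, 260 of named genotype genes and 129 of named piece genes, and gained in 13 of lists. Depth limits the immunoglobulin V shares of SB, with 564 heavy chain V and 94 lambda V counts in piece 2 of SB animal 1. On simulated counts the genotype test recovered 1.49% of 2-fold changes with the spread of these animals and 83.6% with that of the controls alone, each applied to both genotypes.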

Other observations

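The test of strain segments among the controls was chosen only after the result was seen, and so were the genes named here, apart from their membership in the fixed lists. Several single genes with known roles in blood stood out in 1 SB spleen in both pieces. Ets1, a lymphoid and endothelial transcription factor, stood at 2128 and 2039 CPM in the pieces of SB animal 3, 66.4 to 88.5 in the other SB pieces and 807 to 1014 in control pieces. Epo, which encodes erythropoietin, stood at 8.41 and 8.97 CPM in SB animal 3 and at most 0.217 in any other library. Hbb-y, an embryonic globin, stood at 249 and 238 CPM in SB animal 1 and at most 3.45 elsewhere. Gzmb, a granule protease of cytotoxic cells, stood at 912 CPM in SB animal 1, 11.1 and 1.25 in SB animals 2 and 3 and at most 3.62 in controls, while Ncr1, a receptor of NK cells, stood at 0.333 CPM in SB animal 1 and 4.41 ± 0.371 in controls (SD, n = 3). Siglec1, a macrophage lectin, stood at 1409 CPM in SB animal 2, 8.51 and 23.6 in SB animals 1 and 3 and 27.0 ± 4.58 in controls.

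Among the 73 genes that differed between control animals, 22 were immunoglobulin genes. Of the other 51 genes, 19 lay within 1 Mb of another, where 10000 random draws of tested genes gave a median of 4 and at most 16 (permutation, one-sided p = 1e-04, the smallest these draws can give). This is consistent with segments of another strain in some controls. Of these genes 6 belong to the interferon-inducible Ifi200 family on chromosome 1 (173468485 to 173942491, GRCm38), such as Ifi204 at 35.0 and 35.7 CPM in control animal 1 and at most 10.97 in the other controls, and neighbouring family members may also be regulated together or share reads, which the test does not separate. Apobec3 on chromosome 15, a cytidine deaminase, stood at 53.1 and 59.9 CPM in control animal 1 and at 305 to 319 in the other controls.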
